A study of Glycine max with 16 samples.

How the data were processed

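Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was applied to embryos of soybean (Glycine max, cultivar Williams 82) to map the chromatin sites of LEAFY COTYLEDON1 (LEC1). Per the labels, 16 libraries were made: 8 immunoprecipitated (ChIP) libraries and 8 libraries of total chromatin (input), with 2 biological replicates in each of 8 groups. Embryos came from 3 stages. Cotyledon-stage embryos (COT) were taken from seeds 2.5 to 3.5 mm long, early maturation embryos (EM) from seeds 6 to 7 mm long, and mid-maturation embryos (MM) from seeds of 200 to 250 mg. An antibody raised against recombinant GmLEC1 protein was used at all 3 stages, and a second antibody, raised against a GmLEC1 peptide, was used at EM. Per the labels' protocols, tissue was fixed in 1% formaldehyde for 10 minutes, chromatin was sheared to 100 to 500 bp, 3 ug of antibody was used, and libraries were amplified with 15 PCR cycles.

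The deposited files are 4 peak lists, 1 for each stage with the anti-recombinant antibody and 1 for EM with the anti-peptide antibody. Each row gives a chromosome, a start, an end, a name and a score that the authors computed. Bowtie 0.12.7 and SAMtools 0.1.19 are named in the submitters' processing notes. The peak caller, its threshold, the meaning and scale of the deposited score, and whether the 2 replicates were pooled are not given in the sources used here. The peak names carry Gmax275 as the genome build. The score was therefore used only to rank, filter and describe peaks within its own list, and never compared in size between lists. Reads per library are not given in these files, so the sequencing depth behind each list is unknown and no interval or detection limit based on depth could be given. With 1 list per stage and antibody, no spread between biological replicates could be measured. All intervals and p-values below measure consistency along the genome for these 4 lists and not the reproducibility of the experiments.

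All starts and widths in the lists are multiples of 50 bp when the end is read as the last base of a 50 bp bin, and the lists were read that way. Positions are given 1-based. The genome sequence and gene annotation of this build were not used here. The gene table at hand is of another assembly, so peaks were not assigned to genes, and the planned tests on promoters, gene lists and sequence motifs were not run. Regions are named by position instead: the rule fixed before the data were examined gives, without an annotation of the build, the 5 highest-scoring peaks of each list. All other positions named were chosen after their values were seen.

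Peaks were taken as shared when they overlapped by at least 1 bp. The share of one list's peaks overlapped by the other was set against 1000 random placements of the other list's peaks within their own 1 Mb windows, which keeps the regional density and the widths. The two-sided placement p cannot fall below 0.002. The last peak end over all lists stood for the length of each chromosome or scaffold, and placement did not exclude unmappable sequence. Intervals (95%) come from 10000 bootstrap draws of chromosomes, with scaffolds as 1 block where they were included. Overlap between pairs of lists was compared with the Jaccard index, the shared peaks (mean of both lists) over the union, computed for each of the 20 chromosomes. Differences were tested with a two-sided permutation test of 100000 sign flips over chromosomes, whose smallest p is 1e-05. Benjamini-Hochberg adjustment was made over the 4 overlaps, over the 4 differences of Jaccard indices and over 6 list pairs for strong peaks. Merged regions over the 3 stages were built by joining overlapping anti-recombinant peaks, and their share with an anti-peptide peak was set against 200 placements. Exact binomial (Clopper-Pearson) intervals are given where named and cover counting error only. Score agreement is Spearman's rho over peaks that overlapped 1 partner each, with 500 bootstrap draws of chromosomes.

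Alternatives fixed before the data were examined were a reciprocal overlap of at least 50%, midpoints within 100 bp, the higher-scoring 50% of each list, equal list length (the 49566 highest-scoring peaks of each list), placement on the whole chromosome, and chromosomes without scaffolds. The comparison of the peptide list with each stage, the sites of 1 stage only, the strong peaks without a partner, the score agreement, the merged regions, the counts of neighbouring peaks and the window counts were added after the data had been examined. A binomial comparison of peak numbers in 100 kb windows was also computed and is not reported, because it treats the mostly shared peaks of a pair of lists as independent and could hardly have found a difference. The overlap code was tested on simulated lists of 20000 positions, in which planted shared shares of 30, 60 and 90% were recovered to within 0.639 percentage points of expectation. Of the 5 simulated pairs with nothing planted, 0 fell under the 0.05 threshold, and 5 of 100 simulated sign-flip tests without a difference did. The unplanted lists were placed within 1 Mb windows, as in the random placements themselves, and the sign-flip tests used independent normal values. These checks therefore test the code and not how the tests behave for peaks clustered below 1 Mb. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.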

Results

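LEC1 is a subunit of the CCAAT-binding nuclear factor Y complex and a central regulator of embryo development and seed filling in plants. Its binding sites in soybean embryos were mapped at the cotyledon (COT), early maturation (EM) and mid-maturation (MM) stages with an antibody against recombinant GmLEC1. At EM they were mapped a second time with an antibody against a GmLEC1 peptide. The data are 4 peak lists, each from ChIP libraries of 2 biological replicates with their inputs. The COT list held 51845 peaks, the EM list 55140, the MM list 64146 and the EM peptide list 49566. The median peak width was 300 bp at COT and EM and in the EM peptide list, and 350 bp at MM. Peaks covered 16.0 Mb at COT, 19.2 Mb at EM, 23.0 Mb at MM and 17.2 Mb in the EM peptide list, which is 1.67 to 2.40% of the sequence spanned by the lists. Wider peaks scored higher in every list, with Spearman's rho across peaks of 0.844 to 0.881. The libraries' depth is unknown, so the different lengths of the lists are not measures of how much LEC1 was bound at a stage.

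LEC1 peaks were concentrated towards the chromosome ends at all 3 stages and with both antibodies. The outer 20% at either end held 68.9% of the COT peaks on chromosomes, 68.8% of the EM peaks, 68.3% of the MM peaks and 68.8% of the EM peptide peaks. The chromosome centres, from 25 to 75% of the length, held 21.4 to 21.9%. Mappable sequence and genes along the chromosomes were not measured, so this profile cannot be told apart from one common to other peak lists. Chromosome 13 had the highest density in each list, with 84.8 peaks per Mb at COT, 87.6 at EM, 99.8 at MM and 77.1 in the EM peptide list. Chromosome 18 was the sparsest at COT (41.0 per Mb) and in the EM peptide list (40.0), and chromosome 1 at EM (45.1) and MM (52.5). The densest 1 Mb window lay at positions 3000001 to 4000000 of chromosome 6 at COT, with 197 peaks, and at MM, with 211. The same interval of chromosome 11 was the densest at EM, with 193 peaks, and in the EM peptide list, with 184. Across the 956 windows of 1 Mb, peak numbers of any pair of lists had a Spearman's rho of 0.990 to 0.994; windows are not independent replicates. Unplaced scaffolds held 256 to 333 peaks per list.

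**Figure D1:**
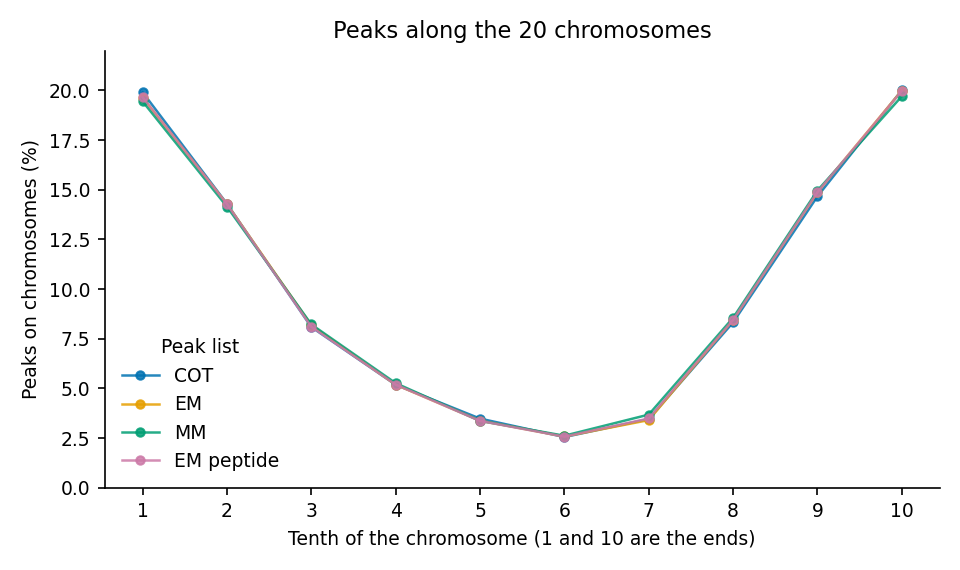
Percentage of each list's chromosomal peaks (vertical axis) in each of 10 equal parts of the chromosome length (horizontal axis), over the 20 chromosomes, one line per peak list. The 4 lines nearly coincide: each falls from at least 19.4% in the parts at the ends to 2.55 to 2.62% in the sixth part.

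Peaks also lay close to one another. At COT 31.2% of peaks had another within 1 kb, against 22.8% ± 0.226 (SD over placements) when the same peaks were placed at random within 1 Mb. The corresponding shares were 32.8 against 24.3% at EM, 35.0 against 27.3% at MM and 29.1 against 22.3% in the EM peptide list. Each two-sided permutation p from 1000 placements was 0.002, the smallest they allow. Placement within 1 Mb keeps no density on finer scales and did not exclude unmappable sequence, and narrower windows were not tried for neighbours. The excess therefore shows only that peaks were unevenly spread below 1 Mb.

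The 5 highest-scoring sites of each list were found in all the others. The first COT peak lay on chromosome 8 at positions 16773601 to 16774200 and took place 5515 in the EM list, 2855 in the MM list and 1413 in the EM peptide list. The COT peak at positions 13050101 to 13051000 of chromosome 16 was in second place at COT, and the MM peak over it, at 13050051 to 13051100, was in second place at MM. It took place 1785 at EM and 2042 with the peptide antibody. The other COT peaks among the first 5 lay on chromosome 18 at 2729951 to 2730500, chromosome 13 at 38404401 to 38404850 and chromosome 5 at 8660351 to 8660900. The first EM peak, on chromosome 12 at 6694501 to 6695250, took place 17 in the EM peptide list, 967 at COT and 1357 at MM. The second, on chromosome 13 at 20574851 to 20575550, was within the first 106 peaks of every list. EM places 3 and 5 were on chromosome 16 at 32472501 to 32473100 and chromosome 11 at 15767251 to 15767950. The EM peak in place 4, on chromosome 20 at 11231651 to 11232250, took place 2030 at MM and 3653 at COT but 30816 with the peptide antibody.

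The first MM peak lay on chromosome 2 at 12247301 to 12247850, and took place 2233 at COT, 745 at EM and 3905 with the peptide antibody. The MM peak in place 3, on chromosome 14 at 9720251 to 9720900, was in place 4 of the EM peptide list, at 9720301 to 9720900. MM places 4 and 5 were on chromosome 17 at 2024801 to 2025550 and chromosome 4 at 8125751 to 8126250, the latter in place 17 at COT and 71 at EM. The other leading EM peptide peaks were on chromosome 15 at 22027701 to 22028300 and 13219051 to 13219700, chromosome 2 at 39062551 to 39063400 and chromosome 9 at 5118201 to 5118950. The lists differ in length, and a different place does not show a change in binding.

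The first question was how far the sites of LEC1 persist from stage to stage. Most peaks were shared between stages. Of the COT peaks, 75.4% (95% interval 75.02 to 75.9) were overlapped by an EM peak and 79.0% (78.6 to 79.5) by an MM peak. Of the EM peaks, 86.9% (86.5 to 87.2) were overlapped by an MM peak and 70.2% by a COT peak. Of the MM peaks, 74.5% were overlapped at EM and 63.2% at COT. Randomly placed peaks overlapped 6.20% ± 0.101 (SD over placements) of COT peaks for EM, 7.21% ± 0.111 of COT peaks for MM and 7.59% ± 0.107 of EM peaks for MM. The observed shares were 12.2, 10.96 and 11.4 times as high, each with a two-sided permutation p of 0.002 (adjusted 0.002), the smallest the placements can give. With placement within 20 kb, added later, they were 7.61, 7.13 and 7.31 times as high. Random placement cannot tell shared sites of LEC1 from other regions that both lists hold. With lists of equal length EM shared 80.9% of its peaks with MM, and COT shared more with EM (73.3%) than with MM (70.7%), the opposite order to the whole lists.

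Sharing followed the score. In the highest-scoring 10% of the COT list, 99.8% of peaks were overlapped at EM and 99.9% at MM, and in the lowest-scoring 10% it was 40.5 and 48.4%. In the EM list the highest-scoring 10% was overlapped by COT for 98.4% and by MM for 5514 of 5514 peaks, and the lowest for 38.2 and 58.7%. In the MM list the highest-scoring 10% was overlapped by COT for 96.4% and by EM for 99.9%, and the lowest for 32.2 and 34.7%. Peaks that no other stage overlapped numbered 8134 at COT (15.7%), 4503 at EM (8.17%) and 11965 at MM (18.7%). Their median width was 150 bp at COT and EM and 200 bp at MM, against 300 bp for the shared COT peaks and 350 bp for the shared EM and MM peaks. Their median score was lower than that of shared peaks by 0.529 at COT (95% interval 0.517 to 0.538), by 0.727 at EM (0.715 to 0.738) and by 0.962 at MM (0.947 to 0.976), in the authors' units of each list. Among the highest-scoring 10%, 1 COT, 0 EM and 5 MM peaks were without a partner at either other stage. Under reciprocal overlap these counts were 59, 37 and 72. Where peaks of different stages overlapped 1 to 1, their midpoints were a median of 25 bp apart for each pair of stages, and Spearman's rho of their scores was 0.735 (0.729 to 0.739) for EM and MM. It was 0.6003 (0.594 to 0.606) for COT and EM and 0.606 (0.5999 to 0.613) for COT and MM. These correlations run across peaks, which are not independent replicates.

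**Figure D2:**
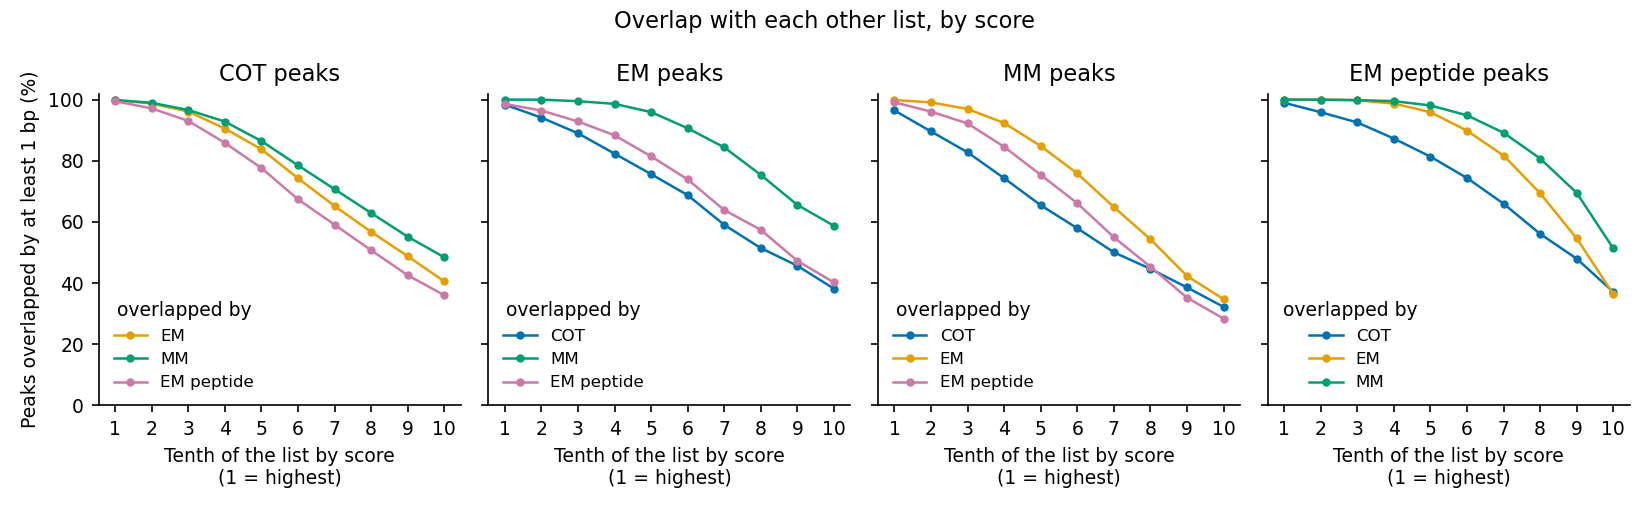
Percentage of peaks overlapped by at least 1 bp by a peak of each other list (vertical axis), in 10 equal parts of the list in order of the authors' score (horizontal axis, 1 is the highest); one panel per list, one line per other list. All lines start between 96.4 and 100% and end between 28.4 and 58.7%.

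The peaks of the 3 stages merged into 78759 regions. Of these, 35935 (45.6%) were called at all 3 stages. A further 11416 (14.5%) were called at EM and MM and not COT, 4234 (5.38%) at COT and MM and not EM, and 2572 (3.27%) at COT and EM and not MM. Regions called at 1 stage numbered 8134 at COT, 4503 at EM and 11965 at MM. Regions of all 7 combinations had 20.4 to 23.4% of their members in the chromosome centres.

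More strong peaks of the MM and EM lists lacked a COT peak than the reverse. With lists of equal length, 147 of the 5000 highest-scoring MM peaks (2.94%) had no COT peak, against 17 of the 5000 highest-scoring COT peaks (0.34%) without an MM peak. EM gave the like result, with 84 EM peaks without COT against 13 COT peaks without EM. For MM and EM the counts were 3 MM peaks without EM and 1 EM peak without MM. MM exceeded COT on 19 of 20 chromosomes and COT exceeded MM on 0 (p = 1e-05, the smallest possible, adjusted 2e-05, two-sided permutation test over chromosomes). EM exceeded COT on 19 of 20 (adjusted p = 2e-05, same permutation test), and for MM and EM the permutation p was 1. The EM peptide list, too, had more strong peaks without COT (57) than the reverse (23; adjusted p = 0.000264, permutation test). Lists of the same stage also differed: 70 EM anti-recombinant peaks had no EM peptide peak, against 0 in the reverse (adjusted p = 2e-05, permutation test). Likewise 32 MM peaks had no EM peptide peak, against 0 in the reverse (more on 17 of 20 chromosomes, adjusted p = 3e-05, permutation test). Under reciprocal overlap the counts were higher in both directions and less one-sided: 527 against 121 for MM and COT, 380 against 147 for EM and COT, 292 against 161 for the EM peptide list and COT, 276 against 76 for EM and the EM peptide list, and 182 against 57 for MM and the EM peptide list. MM and EM differed under reciprocal overlap, by 35 (permutation p = 0.0039), and among the top 10000, by 30 (permutation p = 0.0015). Among the top 1000 the counts were 8 EM peaks without COT against 1 in the reverse, and 3 MM peaks without COT against 0. The counts differed on 5 and 3 chromosomes, too few for the permutation test to go below 0.062 and 0.25, the values it gave. With 1 list per stage, stage and experiment are confounded in these counts.

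Against the whole COT list, 139 of the top 5000 MM peaks had no COT peak. They lay on all 20 chromosomes, with at most 14 on 1 chromosome, and 26.6% of them were in the chromosome centres, against 21.8% of all top 5000 MM peaks. Of the 139, 137 had an EM peak (98.6%, exact 95% interval 94.9 to 99.8) and 127 an EM peptide peak (91.4%, 85.4 to 95.5). Both shares were below those of all top 5000 MM peaks, of which 99.96% had an EM peak and 99.36% an EM peptide peak. Of the top 5000 EM peaks, 78 had no COT peak, and 78 of these had an MM peak and 66 an EM peptide peak (84.6%, 74.7 to 91.8), against 98.6% of all top 5000 EM peaks with an EM peptide peak. The highest-scoring of the EM sites, a position chosen after the values were seen, lay on chromosome 3 at 1665501 to 1666100, in place 148 at EM, 1608 at MM and 741 with the peptide antibody. The next, on chromosome 6 at 16966401 to 16967050, was in place 240 at EM, 2702 at MM and 3467 with the peptide antibody. The highest-scoring MM sites without a COT peak, chosen likewise, lay on chromosome 11 at 10486201 to 10486600 (place 514) and chromosome 7 at 17420701 to 17421300 (place 540). In the other direction 6 of the top 5000 COT peaks had no MM peak and 6 no EM peak. The one without either, on chromosome 1 at 53107501 to 53107950 and in place 4137, had no EM peptide peak.

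**Figure D3:**
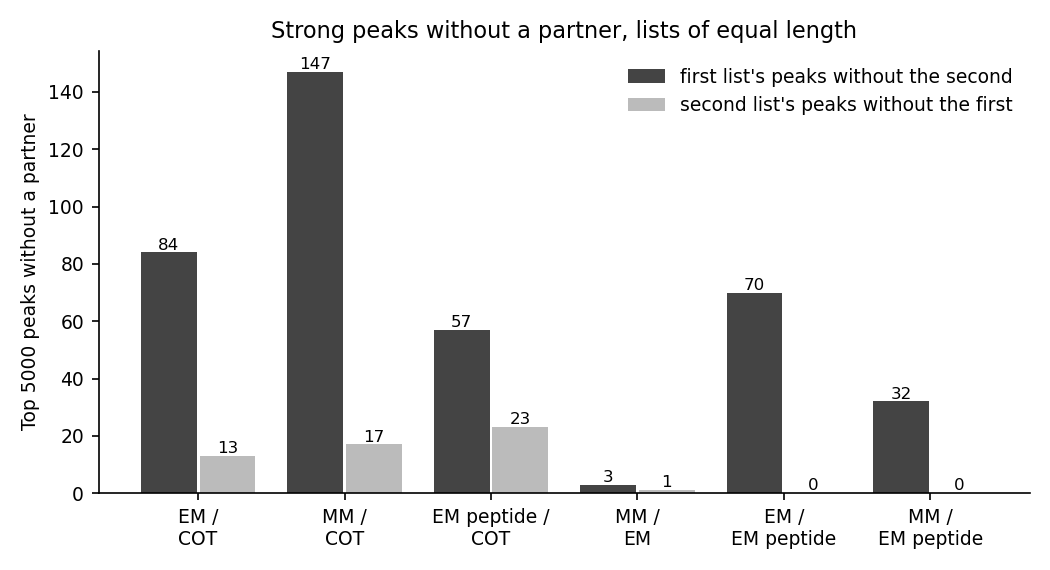
Number of the 5000 highest-scoring peaks of one list that no peak of another overlaps (vertical axis), for 6 pairs of lists cut to 49566 peaks each (horizontal axis); dark bars give the first-named list's peaks without the second and light bars the reverse. MM without COT reaches 147 and COT without MM 17, and the same-stage pair of antibodies at EM shows 70 and 0.

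The second question was how far the antibodies against recombinant protein and peptide mark the same sites at EM. Of the EM peptide peaks, 82.6% (82.2 to 83.0) were overlapped by an EM anti-recombinant peak, 12.6 times the 6.56% ± 0.105 (SD over placements) of random placement (adjusted permutation p = 0.002, the smallest possible). With placement within 20 kb it was 7.76 times as high. In the reverse direction 74.0% (73.5 to 74.5) of the EM anti-recombinant peaks were overlapped. All 4957 peaks of the highest-scoring 10% of the EM peptide list had an EM anti-recombinant partner, and 36.4% of the lowest-scoring 10% had one. Of the highest-scoring 10% of EM anti-recombinant peaks, 98.6% had a peptide partner. Under reciprocal overlap 75 peptide and 316 anti-recombinant peaks of the highest-scoring 10% were without a partner. The 14323 EM anti-recombinant peaks without a peptide partner had a median width of 200 bp, against 400 bp for those with one. Their median score was lower by 0.756 (95% interval 0.743 to 0.768). The 8607 peptide peaks without a partner scored lower than the shared ones by 0.898 (0.884 to 0.910). The 70 anti-recombinant sites of the top 5000 without a peptide peak included chromosome 3 at 35881801 to 35882350 (place 413) and chromosome 5 at 22212901 to 22213400 (place 508), chosen after the values were seen. Of the 70, 70 had an MM peak and 58 a COT peak (82.9%, exact 95% interval 71.97 to 90.8), against 98.44% of all top 5000 EM peaks with a COT peak.

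The overlap of lists that differ in antibody was then compared with that of lists that differ in stage. The Jaccard index of the EM and EM peptide lists was 0.640 ± 0.0082 (SD over 20 chromosomes). It was 0.571 ± 0.0123 for EM and COT and 0.670 ± 0.0098 for EM and MM. EM shared more with the other antibody at its own stage than with COT, by 0.0688 (95% interval 0.0630 to 0.0746; higher on 20 of 20 chromosomes, adjusted p = 1e-05, the smallest possible, two-sided permutation test). It shared less with the other antibody than with MM, the difference being −0.0293 (−0.0336 to −0.0252; lower on 20 of 20 chromosomes, adjusted p = 1e-05, same permutation test). The size of the latter ran from −0.0103 with the higher-scoring 50% of each list to −0.0441 under reciprocal overlap. The EM and MM lists were made with the same antibody. Each list comes from its own ChIP experiment of unknown depth, and none repeats the stage and antibody of another. The index that repeated experiments would give is therefore unknown. A difference between experiments along the whole genome could also give the same sign on all chromosomes. The order of the indices therefore cannot be credited to antibody or stage.

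The EM peptide list allows the lists of the stages to be compared with the antibody differing on both sides. Stage and experiment remain confounded in these comparisons as well. Of its peaks, 82.6% were overlapped by EM, 88.3% by the longer MM list and 73.7% by COT. By the Jaccard index, which counts the peaks of both lists, it was closer to EM than to COT, at 0.640 against 0.566, a difference of 0.0745 (0.0699 to 0.0792; 20 of 20 chromosomes, adjusted p = 1e-05, permutation test). With the lists as deposited it was also closer to EM than to MM, by 0.0190 (0.0150 to 0.0230; 20 of 20 chromosomes, adjusted p = 1e-05, permutation test). That preference did not hold with lists of equal length, where the difference was −0.00394 (−0.00752 to −0.000240; lower on 14 of 20 chromosomes, adjusted p = 0.051, permutation test). With the 10000 highest-scoring peaks of each list it was −0.0332, closer to MM (−0.0457 to −0.0224; 19 of 20 chromosomes, adjusted p = 2e-05, permutation test). Spearman's rho of the scores of 1-to-1 shared peaks was 0.726 (0.722 to 0.730) for the EM peptide list and EM, 0.758 (0.754 to 0.762) for the EM peptide list and MM, and 0.642 (0.634 to 0.649) for the EM peptide list and COT.

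The second antibody found the regions of the 3 stages to very different extents. Of the 35935 regions called at all 3 stages, 89.2% (88.9 to 89.5) had an EM peptide peak, against 7.33% for randomly placed peptide peaks. Of the regions called at EM and MM it was 58.8% (58.0 to 59.6), at COT and MM and not EM 49.6% (47.6 to 51.3), and at COT and EM 38.9% (37.1 to 40.7). Of the regions called at EM alone, 877 of 4503 had a peptide peak (19.5%, 18.2 to 20.7). For MM alone it was 19.6% (18.7 to 20.4) and for COT alone 14.2% (13.6 to 14.9), with 4.30 to 4.44% under random placement within 1 Mb. Narrower windows were not tried for regions. For the whole EM peptide and EM lists, placement within 20 kb raised the placed share from 6.56 to 10.6%, so the excess for regions of 1 stage may be overstated. The EM-only minus MM-only difference was −0.0895 percentage points (−1.26 to 1.25; p = 1, two-sided permutation test over chromosomes), and −1.05 points under reciprocal overlap (permutation p = 0.0083). The EM-only share exceeded the COT-only share by 5.26 points (3.96 to 6.64; permutation p = 2e-05); these p-values were not adjusted. The shares depended on the setting. At equal list length they were 30.9% for EM alone, 30.9% for MM alone and 22.4% for COT alone, and among the higher-scoring 50% of peaks 39.8, 36.9 and 24.0%. The EM-only minus COT-only difference was then 8.47 points (permutation p = 1e-05) and 15.8 points (permutation p = 0.0085), and under reciprocal overlap 2.99 points (permutation p = 1e-05).

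**Figure D4:**
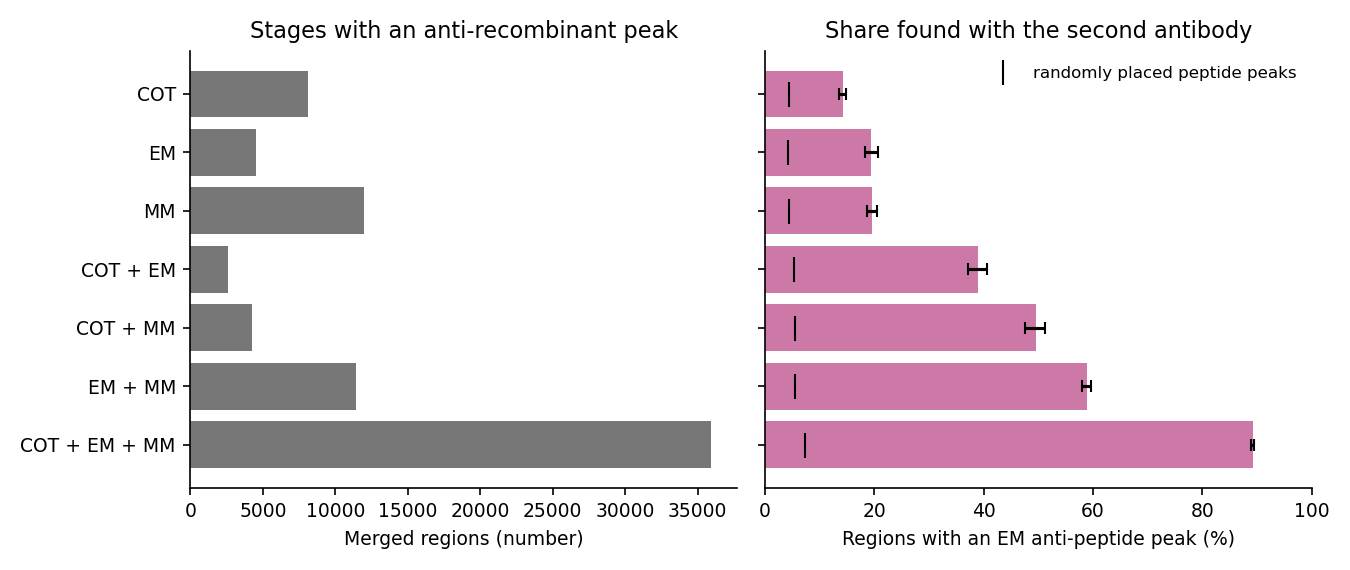
Left, number of merged regions (horizontal axis) by the stages at which the anti-recombinant antibody gave a peak; right, percentage of those regions with an EM anti-peptide peak, with 95% intervals from resampled chromosomes, and ticks for randomly placed peptide peaks. The share rises from 14.2% of COT-only regions to 89.2% of regions called at all 3 stages, and EM-only and MM-only regions stand at 19.5 and 19.6%. Median region width also rises, from 150 bp for COT-only regions to 450 bp for regions of all 3 stages.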

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

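The comparisons of the EM list with the EM peptide, COT and MM lists were fixed before the data were examined; the comparisons of the peptide list with each stage and of strong peaks, and all tests of explanations in this part, were chosen after the results had been seen. The 3 differences in this part stood out because the difference itself passed a permutation test over chromosomes.

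The EM list shared more with the EM peptide list than with COT (difference of Jaccard indices 0.0688) and less than with MM (−0.0293), while the peptide list as deposited was closer to EM than to MM by 0.0190. Unequal list length is a candidate explanation of that last difference, which was −0.00394 with equal numbers of peaks. The larger distance to COT was not removed that way: at equal length the peptide list was closer to EM than to COT by 0.0731. Binding sites that differ between stages could give such a distance, and so could a COT experiment that differed from the others; with 1 list per stage these cannot be told apart.

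The count of strong MM peaks without a COT peak exceeded the reverse count by 130 at equal list length. The tables argue against unequal list length as the whole cause, since the ratio of the counts at equal length was 8.65 (4.36 under reciprocal overlap and 5.05 among the top 10000). Experiments of unequal sensitivity are a candidate explanation. The 2 lists of EM, made with different antibodies, were lopsided too. There, 70 strong EM peaks were missing from the peptide list and 0 in reverse (276 and 76 under reciprocal overlap). That pair differs in antibody, while the COT and MM lists were made with the same one. It therefore cannot show whether experiments with the same antibody differed in sensitivity. Binding that begins after the cotyledon stage stays open: of the strong MM sites without a peak in the whole COT list, 91.4% had a peak with the second antibody at EM, but so did 99.36% of all strong MM peaks, so the value does not speak for a later onset. With 1 list per stage, stage and experiment are confounded.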

How the results depend on the processing

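No paired analysis was possible because each stage and antibody has 1 peak list, with no values per replicate; for the same reason no replicate could be left out. The promoter, gene, gene-list and motif tests fixed before the data were examined were not run, since the genome and annotation of the build were not used here. Under the 35 other alternatives fixed then, the 4 overlaps and the 2 differences of Jaccard indices for the EM list kept their direction and their side of the 0.05 threshold, and the 5 score differences between shared and list-specific peaks their direction. The 4 overlaps were so far above random placement that their call could hardly have changed. Placement on the whole chromosome leaves the observed share itself unchanged. Over these alternatives the share of the shorter list's peaks ranged from 63.3 to 75.4% for COT and EM and 65.8 to 79.0% for COT and MM. It was 77.5 to 86.9% for EM and MM and 71.7 to 82.6% for the antibodies. Each was lowest under reciprocal overlap of 50%. The 10000 highest-scoring peaks, added later, gave 61.3, 61.3, 69.7 and 68.8%. Both lists were cut there, so a partner ranked below 10000 counted as absent. These values therefore do not show that strong peaks were shared less. Placement within 20 kb still left the observed shares 7.13 to 7.76 times the placed ones. Shares of the longer list were lower. Under reciprocal overlap 59.5% of EM and 53.2% of MM peaks were shared with COT. For MM peaks with EM it was 66.6%, and for EM peaks with the EM peptide list 64.4%. The alternatives below were added after the data had been examined. The peptide list's preference for EM over MM remained with the higher-scoring 50% of each list (0.00676), was lost under reciprocal overlap (0.00172, permutation p = 0.35) and changed sign with equal list length (−0.00394), with the Jaccard index of base pairs (−0.000883, permutation p = 0.43) and with the 10000 highest-scoring peaks (−0.0332); its preference for EM over COT did not change call under any of the 5 settings tried. The difference between EM-only and MM-only regions was 2.98 points among the higher-scoring 50% of peaks (permutation p = 0.53) and −1.05 under reciprocal overlap (permutation p = 0.0083), while EM-only minus COT-only kept its direction and call, at 2.99 to 15.8. For strong peaks, the top 1000 gave differences in the same direction of 7 for EM against COT (ratio 8, against 6.46 in the top 5000), 3 for MM against COT, 5 for the peptide list against COT, 5 for EM against the peptide list and 1 for MM against the peptide list; the counts differed on at most 5 chromosomes, where the permutation test cannot go below 0.062, so the lost calls say nothing of a weaker difference. MM against EM passed it under reciprocal overlap (35) and with the top 10000 (30). The cause of the other changes was not tested. Unknown depth limits all comparisons of list length.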

Other observations

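The regions that the anti-recombinant antibody gave at COT and MM but not at EM numbered 4234, and 2098 of them had an EM peak with the peptide antibody (49.6%, against 5.42% under random placement). For these 2098 regions the absence from the EM list did not hold with the second antibody. The 11416 regions of EM and MM without COT had a median width of 350 bp, against 450 bp for the regions of all 3 stages and 150 to 200 bp for those of 1 stage.

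The comparison of regions called at 1 stage was added after the data had been examined, and its 2 tests here were set down before their results were seen. EM-only regions had a peptide peak in 19.5% of cases and MM-only regions in 19.6%, although the peptide antibody was used at EM; at equal list length both were 30.9%. A surplus of EM-only regions in the chromosome centres is argued against, since their share there was 0.953 times that of regions of all 3 stages. The shares were 20.4% for EM-only, 23.4% for MM-only and 21.4% for regions of all 3 stages. Repeats were not mapped, so an origin in repeats was not tested. Weak peaks near the calling threshold could be a source, but this stays open: among the higher-scoring 50% of peaks the EM-only share exceeded the MM-only share by 2.98 percentage points, with an interval from −6.85 to 12.5 over 118 EM-only peaks. No biological explanation was tested.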
